A study of Heterocephalus glaber with 2 samples.

How the data were processed

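Total RNA was purified from full-thickness dorsal skin of naked mole-rats, and per the labels' protocols only samples with an RNA integrity number above 7.5 were used. Per the labels, ribosomal RNA was removed with the Ribo-Zero Gold kit and paired-end reads of 2 × 150 bases were made on a HiSeq 4000. The submitters' processing notes name cutadapt, FastQC, Bowtie2 and TopHat2 without versions. The genome build, the annotation and the tool that made the gene values are not given in the sources used here. The authors deposited FPKM values, fragments scaled to the length of the locus and the size of the library, with 1 value per locus in each of 4 tables. The tables list the same 24514 loci in the same order and hold a floor of 0.0001 FPKM, at which 4609 loci lay in all 4 libraries. Many loci carry assembled identifiers (18994 of them begin with MSTRG) beside a gene name.

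GEO records 1 sample per age, 4 and 19 years, with 2 tables each, and each table was taken as 1 library. Low FPKM values showed no steps of whole reads, so depth is unknown, no counting error could be given, and no test for counts was used. No 2 libraries shared an identical value above the floor. Gene symbols came from the tables for 13663 loci, and for 1413 more from a RefSeq gene table of the assembly H.glaber_assembly_v1.0 by NCBI gene number. Of the rest, 2439 were small structural RNAs, 254 joined several genes and 6745 had no symbol. No coordinates are given, because the build of the tables is not stated. Genes with near-identical copies, such as globins, histones and MHC genes, may share reads in ways the tables do not show.

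The comparison of old with young libraries used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) for the 12753 loci with a mean of at least 1 FPKM, with the age as the single term, a mean-variance trend in the moderation, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which understates the change of low genes. Gene lists for skin cell types, matrix, ageing and stress, 43 in all, were fixed before the data were examined, as were the design, the other settings to be tried and the rule for naming genes. A list with at least 5 tested members, 39 of them, was tested with camera at its preset correlation of 0.01 with adjustment over the lists, and also with an estimated correlation and with fry. With an estimated correlation camera also took its degrees of freedom from the residuals of the fit, 2, or 1 with the number term. Low p-values are then hard to reach for any list, whatever its correlation. Fry tests whether a list's genes move one way and does not compare them with other genes. Where several loci carried a symbol, the one with the highest mean was used.

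The rule named the 10 genes per direction with the largest change among those that passed with non-overlapping ages and a symbol, filled by the lowest unadjusted p where fewer passed, then up to 4 passing members or else 2 of lowest p per list, and for cell types the 2 with the highest mean. COL3A1, COL5A2, COL6A1, COL4A1, MSTRG.33704, ANGPTL4, TRIM63, MT2A, FKBP5, HLA-DRA and HLA-DQA1 fall outside it and were chosen after their values were seen. Some genes that the rule names are left out of the text. SD is not given for 2 libraries, and each library's value is printed in its place.

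The library numbers split the libraries by RNA composition, so the comparison was repeated with the number as a term and within each number. Within a number, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The fits were tested on simulated data, 5 sets of values for the 12753 genes with the observed number effect, the spread of the fit with the number term and 200 genes changed by 2 or 4 on the log2 scale. Of random lists in these simulated data, 0.3% without and 0.5% with the number term had a camera p under 0.05. Random lists need not hold genes that move together, so these rates do not test the preset correlation for the fixed lists. Among called lists the estimated correlation ran from -0.0081 (melanocyte) to 0.60 (B cell and plasma cell). Other settings chosen beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, no trend, robust moderation, other thresholds, each library left out, the number as a term, and the other list tests. Added after seeing the data were combinations with the number term, the removal of small structural RNA and mitochondrial loci, and lists without some members. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. After the data were seen, 4 more lists were made for the closing section, with no member that a fixed list holds. They cover collagen folding and secretion, fatty acid oxidation and fasting, the glucocorticoid response and MHC class II presentation. The SE over genes of their medians is a bootstrap over members within 1 pair of libraries. It treats members as independent and holds no spread between libraries.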

Results

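Full-thickness skin from the back of naked mole-rats (Heterocephalus glaber), long-lived subterranean rodents, was profiled by RNA sequencing at a young age of 4 years and an old age of 19 years, to ask how the skin transcriptome differs with age. Each age had 2 libraries, called young 1, young 2, old 1 and old 2 after the numbers in the deposited tables. The labels do not say whether the 2 libraries of an age came from different animals. Every p-value of a single gene therefore measures only the spread between these libraries, which may be technical. A camera p-value at the preset correlation sets the genes of a list against the other genes. It rests on the spread across genes and is no evidence from replicate animals. Values were FPKM for 24514 loci, and the number of reads behind them is unknown. They summed to 401039 in young 1, 425548 in young 2, 445064 in old 1 and 406522 in old 2. Above the floor value of 0.0001 FPKM lay 18195 loci in young 1, 16365 in young 2, 18441 in old 1 and 16127 in old 2.

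The libraries differed more by number than by age. Small structural RNAs such as spliceosomal and nucleolar RNAs held 46.8% of the summed FPKM in young 1 and 51.1% in old 1. The same loci held 0.0961% in young 2 and 0.330% in old 2. Mitochondrially encoded genes held 5.77% and 4.06% in the number 1 libraries and 23.2% and 29.6% in the number 2 libraries, young before old. Across 12753 genes, log2 values correlated at 0.948 between young 1 and old 1 and at 0.927 between young 2 and old 2, but at 0.712 between the young libraries and 0.701 between the old ones. Genes are not independent replicates, so these correlations describe the libraries. The first principal component held 82.0% of the variance and separated the numbers. The age comparison is therefore given also within each number, as old 1 over young 1 and old 2 over young 2, each a comparison of 1 library with 1 library that has no replicate check.

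Transcripts of the main dermal collagens were many times lower in the old libraries. COL1A1, the alpha 1 chain of type I collagen, stood at 2079 FPKM in young 1, 4121 in young 2, 196 in old 1 and 41.4 in old 2. COL3A1, the chain of type III collagen, stood at 2734, 2623, 223 and 20.8 FPKM in the same order. SPARC, a collagen-binding matrix protein, stood at 1703, 3461, 160 and 85.9 FPKM. PDK4, a kinase that turns pyruvate away from oxidation, stood at 15.1, 3.07, 48.2 and 161 FPKM. KRT10, the keratin of the upper living epidermis, stood at 1285 and 1323 FPKM in young 1 and old 1 and at 3823 and 3693 FPKM in young 2 and old 2.

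Over all genes, limma on log2(FPKM + 1) called 0 genes higher and 0 lower in old skin among 12753 tested at adjusted p 0.05. At unadjusted p under 0.05 there were 25 higher and 53 lower, and limma without the trend and with robust moderation also called 0 and 0. In simulated data with the same split by number, this fit recovered 0 of 500 genes changed by 2 on the log2 scale and 0 of 500 changed by 4. With the library number as a term, limma called 1 gene higher and 2 lower, each with adjusted p = 0.0134, and 377 higher and 460 lower at unadjusted p under 0.05. In simulated data that fit recovered 95.2% and 96% of genes changed by 2 and by 4, with 24.2 false calls per simulation. Beside 200 changed genes, this is a larger share of false calls than adjusted p 0.05 aims for. These rates do not give the power of the fit in the data, where a gene's ratio could differ between the numbers. That fit did not call COL1A1 (adjusted p = 0.112), with log2 ratios of -3.40 in number 1 and -6.60 in number 2. It called 0 and 0 when the small structural RNA and mitochondrial loci were left out and the rest rescaled (lowest adjusted p = 0.0661), where the log2 differences of the genes it had called lower were close to those before, -4.25 against -4.31 for C1QTNF6 and -4.12 against -4.17 for CPZ. Leaving out 1 library at a time unbalanced the numbers against the ages and gave 24 higher and 7 lower calls without young 1, 0 and 2 without young 2, 6 and 32 without old 1, and 0 and 0 without old 2. The old libraries both lay on one side of the young ones for 1755 genes, 13.8% of those tested, where chance gives 33.3% for 4 exchangeable libraries. These libraries were not exchangeable, since they split by number, and within the numbers 26.7% of genes were higher in old skin in both and 23.1% lower in both. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33. Across genes, the log2 ratios of the number 1 and the number 2 libraries correlated at 0.165 (Spearman 0.0689).

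The 3 genes called with the library number as a term had large ratios in both numbers. C1QTNF6 (locus MSTRG.34036), a secreted protein of the C1q and TNF related family, fell by 4.31 ± 0.36 (SE) on the log2 scale, from 22.7 and 42.9 FPKM in young 1 and 2 to 0.949 and 0.360 FPKM in old 1 and 2. CPZ (MSTRG.37783), a carboxypeptidase of the extracellular matrix, fell by 4.17 ± 0.36 (SE), from 23.1 and 59.2 FPKM to 1.15 and 1.10 FPKM. The gene that rose was locus MSTRG.33704, for which no symbol was found, at 0.361 and 0.150 FPKM in young skin and 18.2 and 9.37 FPKM in old skin, a log2 difference of 3.49 ± 0.29 (SE). Without that term none of the 3 passed with all 4 libraries. Without young 1 limma called C1QTNF6 (log2 difference -4.75) and CPZ (-4.82) lower, and without old 1 it called them at -4.57 and -4.18. Their log2 differences were -3.86 and -3.51 without young 2 and -4.05 and -4.15 without old 2.

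Because no gene passed without the number term, genes with the lowest unadjusted p in each direction are given as values. Only genes with a symbol and non-overlapping ages were taken, which left out MSTRG.33704. On the higher side, C1QTNF3, another member of the C1q and TNF related family, stood at 0.910 and 0.441 FPKM in young 1 and 2 and at 10.5 and 38.9 FPKM in old 1 and 2. GALNT15, which starts O-linked sugar chains, stood at 4.57 and 2.90 against 17.5 and 36.3 FPKM. CCN3, a matricellular protein, had close ratios in both numbers, 5.50 in number 1 and 5.90 in number 2. PCK1, an enzyme of glucose and glycerol synthesis, stood at 4.00 and 1.32 against 19.7 and 14.0 FPKM. LTBP2, a microfibril-associated protein, stood at 1.18 and 0.419 against 7.85 and 5.44 FPKM. PDK4 differed by 3.46 ± 0.94 (SE) on the log2 scale. The others were ENPP2, which makes lysophosphatidic acid, the cytochrome P450 gene CYP1B1, the muscle gene ANKRD2 and the phosphatase inhibitor PPP1R1A, with log2 differences of 1.54, 1.61, 1.58 and 1.57. C1QTNF3 and PDK4 were called higher without young 1, at log2 differences of 3.89 and 4.45, and without old 1, at 4.59 and 4.32. Neither was called without young 2, at 3.49 and 2.47, or without old 2, at 2.79 and 2.60.

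On the lower side stood C1QTNF6 and CPZ, followed by MMP27, a matrix metalloproteinase, at 9.39 and 13.0 FPKM in young 1 and 2 and 1.02 and 0.230 FPKM in old 1 and 2. CGREF1, a secreted calcium-binding protein, stood at 9.72 and 33.2 against 1.16 and 0.529 FPKM. COL1A2, the alpha 2 chain of type I collagen, stood at 1140 and 1793 against 133 and 23.1 FPKM, and COL5A1, a chain of type V collagen, at 94.5 and 132 against 26.4 and 12.5 FPKM. NDUFA4L2, a mitochondrial protein induced in low oxygen, stood at 13.7 and 61.7 against 2.05 and 2.90 FPKM. CPXM1, a carboxypeptidase-like secreted protein, stood at 8.73 and 13.8 against 2.26 and 2.07 FPKM. COL1A1 was 10.6-fold lower in old 1 than in young 1 and 99.6-fold lower in old 2 than in young 2, and the log2 difference of SPARC was -4.36 ± 1.06 (SE). CGREF1 and NDUFA4L2 were called lower without young 1, at log2 differences of -4.23 and -4.18, and CGREF1 and MMP27 without old 1, at -3.65 and -3.29. In the order CGREF1, NDUFA4L2 and MMP27, the log2 differences were -2.56, -2.09 and -2.72 without young 2 and -3.15, -3.32 and -2.58 without old 2.

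**Figure D1:**
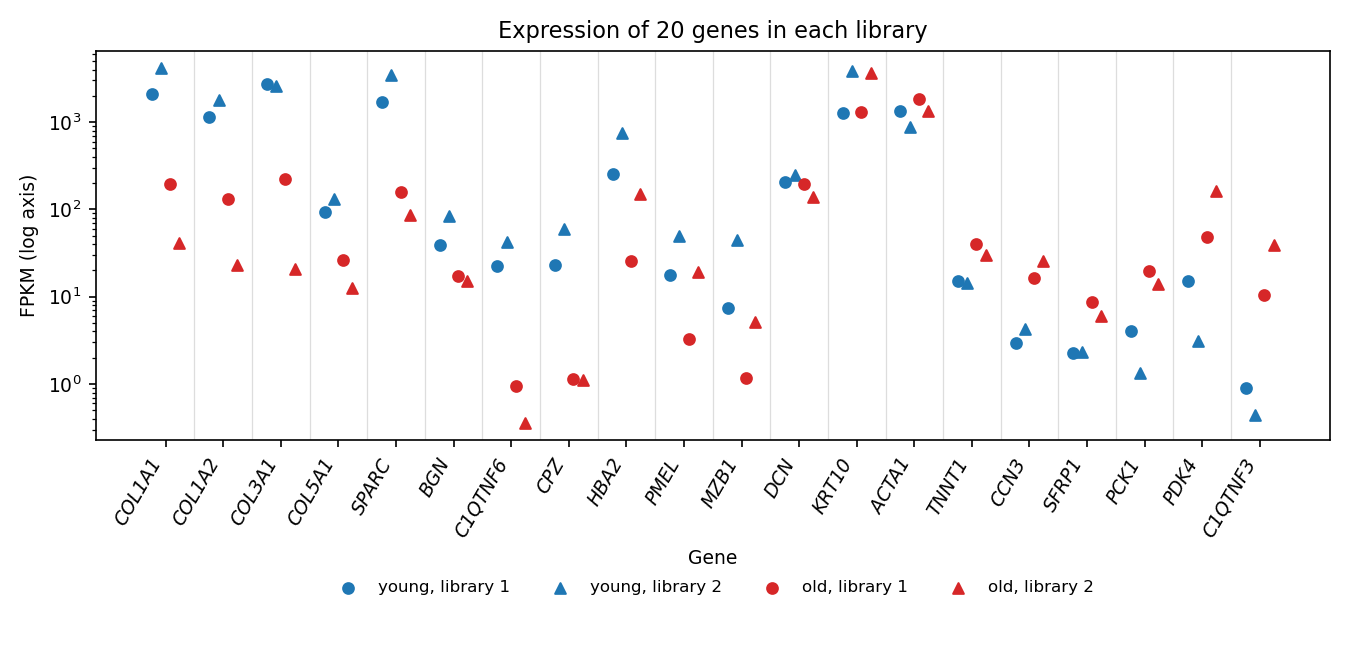
FPKM on a log axis of 20 genes in each of the 4 libraries, with young libraries in blue, old libraries in red, circles for number 1 and triangles for number 2. The collagens, SPARC, C1QTNF6 and CPZ lie lower in both old libraries, with COL1A1 at 196 and 41.4 FPKM against 2079 and 4121 FPKM in the young ones, while KRT10 follows the library number.

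Among 15 tested fibrillar and matrix collagens, 11 were lower in old skin in both numbers and 0 were higher in both, with median log2 ratios of -0.82 in number 1 and -2.31 in number 2. Camera with its preset correlation called the list lower (adjusted p = 8.8e-18), with adjusted p = 0.484 with an estimated correlation. Of its members 0 passed over all genes and 5 passed adjusted over the list alone, COL1A1, COL1A2, COL3A1, COL5A1 and COL5A2, with 10 passing adjusted over the list alone once the library number was a term. Among the other members, COL6A1 stood at 97.1 and 184 FPKM in young 1 and 2 against 54.4 and 29.3 FPKM in old 1 and 2, and COL4A1 of the basement membrane at 50.8 and 38.7 against 45.5 and 43.8 FPKM. The 10 members other than the 5 named chains had medians of -0.39 and -0.46, and the list kept its call without those chains (adjusted p = 1.8e-04). Camera called 11 of 39 lists, 4 higher and 7 lower, and called the same 11 with the library number as a term. With an estimated correlation it called 0, and the collagen list was the only 1 of the 11 that stayed called when each library in turn was left out.

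Proteoglycans were called lower with the preset correlation (adjusted p = 0.0029), with adjusted p = 0.763 with an estimated correlation, and 8 of 18 were lower in both numbers against 4 higher in both. Their median log2 ratio was -0.03 in number 1 and -0.73 in number 2, and 0 members passed over all genes or adjusted over the list alone, where 2 passed with the library number as a term. BGN, or biglycan, stood at 39.0 and 84.4 FPKM in young 1 and 2 against 17.3 and 15.0 FPKM in old 1 and 2, and OGN, or osteoglycin, at 30.1 and 19.8 against 16.4 and 1.06 FPKM. The call ended without young 2 (adjusted p = 0.0823) and without old 2 (adjusted p = 0.658), and OGN was called lower without old 1 (log2 difference -3.63), but had a log2 difference of -0.55 without old 2.

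The remaining matrix lists were not called. The 28 elastic fibre and matrix glycoprotein genes split into 7 higher and 10 lower in both numbers, and held both SPARC and LTBP2 (adjusted p = 0.480). In this list 0 passed adjusted over the list alone, and 7 did with the library number as a term. Of 21 matrix proteases and inhibitors, 8 were higher in both numbers and 7 lower in both (adjusted p = 0.508). MMP27 passed adjusted over the list alone, and 4 members did with the library number as a term. MMP11, or stromelysin 3, stood at 0.735 and 0.494 FPKM in young 1 and 2 and 2.37 and 6.45 FPKM in old 1 and 2. The mean log2 difference of that list was -0.14 while its medians were 0.08 in number 1 and 0.03 in number 2. Hyaluronan metabolism likewise had a mean of -0.10 and medians of 0.13 and 0.14 over 12 genes (adjusted p = 0.825), with HAS2, a hyaluronan synthase, at 7.71 and 1.63 FPKM in young 1 and 2 and 2.42 and 0.660 FPKM in old 1 and 2.

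Markers of dermal fibroblasts, the cells that make these collagens, were called lower with the preset correlation (adjusted p = 2.7e-05), with adjusted p = 0.748 with an estimated correlation. Of 16 members, 11 were lower in both numbers and 0 higher in both. None passed over all genes or adjusted over the list alone, and 2 passed adjusted over the list alone with the library number as a term. The median log2 ratio was -0.06 in number 1 and -0.74 in number 2, and without COL1A2, which the collagen list also holds, -0.05 and -0.65 (adjusted p = 0.0013). Vim, or vimentin, stood at 428 and 559 FPKM in young 1 and 2 and 613 and 459 FPKM in old 1 and 2, and CRABP1, a retinoic acid binding protein, at 2.51 and 16.2 against 1.19 and 0.746 FPKM. The call ended without young 2 (adjusted p = 0.124) and without old 2 (adjusted p = 0.0686).

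Epidermal lists were not called. The 11 basal keratinocyte genes had medians of 0.08 and 0.39 in numbers 1 and 2 (adjusted p = 0.508), with KRT5 at 662 and 1361 FPKM in young 1 and 2 and 700 and 402 FPKM in old 1 and 2. COL17A1, the hemidesmosomal collagen, stood at 40.3 and 25.7 against 38.5 and 85.4 FPKM, and TP63, the epidermal transcription factor, at 14.4 and 7.48 against 7.69 and 2.56 FPKM. The 15 suprabasal and cornified genes had medians of -0.15 and -0.06 (adjusted p = 0.766), and the 6 tested hair follicle genes -0.26 and -0.21 (adjusted p = 0.308). The suprabasal list was called lower without young 1 (adjusted p = 0.0028) or old 2 (adjusted p = 1.3e-04) and higher without young 2 (adjusted p = 0.0039) or old 1 (adjusted p = 0.0135). The 17 sebocyte and epidermal lipid genes had medians of -0.19 and 0.23 (adjusted p = 0.549), with FASN, or fatty acid synthase, at 158 and 52.5 FPKM in young 1 and 2 and 70.0 and 16.2 FPKM in old 1 and 2.

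Pigment cell genes were called lower with the preset correlation (adjusted p = 4.0e-05), with adjusted p = 0.484 with an estimated correlation. That estimate was -0.0081, under the preset 0.01, so the lost call reflects the 2 residual degrees of freedom and not correlation between genes. The estimates for the red cell and p53 target lists, 0.0017 and -0.0054, were also under the preset. Of 11 melanocyte genes, 7 were lower in both numbers and 1 was higher in both, with medians of -0.41 and -0.94. None passed over all genes or adjusted over the list alone, and 5 passed adjusted over the list alone with the library number as a term. DCT, an enzyme of melanin synthesis, stood at 7.96 and 8.49 FPKM in young 1 and 2 and 2.78 and 3.14 FPKM in old 1 and 2. PMEL, the structural protein of pigment granules, stood at 17.9 and 49.3 against 3.30 and 19.2 FPKM, and TYRP1 at 9.87 and 37.0 against 4.65 and 18.8 FPKM. The call ended without young 2 (adjusted p = 0.355) and without old 1 (adjusted p = 0.212).

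Blood and immune transcripts differed by list. The 5 tested red cell genes were called lower (adjusted p = 1.3e-05 with the preset and 0.484 with an estimated correlation), with medians of -1.11 and -1.25. In this list 0 passed over all genes or adjusted over the list alone, and 3 passed adjusted over the list alone with the library number as a term. HBA2, an alpha globin, stood at 258 and 750 FPKM in young 1 and 2 and 25.9 and 150 FPKM in old 1 and 2, and the embryonic globin HBZ at 1.15 and 2.93 FPKM in young skin and at the floor in both old libraries. The 5 tested B cell and plasma cell genes were called lower (adjusted p = 0.0147 with the preset and 0.763 with an estimated correlation), with 3 lower in both numbers and medians of -0.09 and -1.25, and 1 passed adjusted over the list alone with the library number as a term and 0 without it. MZB1, a chaperone of antibody-secreting cells, stood at 7.50 and 45.0 against 1.18 and 5.11 FPKM, while XBP1, which that list also holds, is expressed in many secretory cells and stood at 28.7 and 53.3 against 59.8 and 44.1 FPKM. The red cell call ended without young 2 (adjusted p = 0.118) and without old 1 (adjusted p = 0.122), and the B cell call ended without old 1 (adjusted p = 0.273), turned to the higher side without young 2 (adjusted p = 0.949) and ended with no filter on low values (adjusted p = 0.0676). MZB1 was called lower without young 1 (log2 difference -3.66), but had a log2 difference of -1.22 without young 2.

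The 22 macrophage and dendritic cell genes were not called (adjusted p = 0.327), with medians of -0.26 and 0.12. CD207, or langerin, the marker of Langerhans cells, stood at 12.4 and 19.96 FPKM in young 1 and 2 and 6.29 and 5.71 FPKM in old 1 and 2. C1QA of tissue macrophages stood at 53.6 and 191 against 51.2 and 300 FPKM. The 10 mast cell and granulocyte genes had medians of 0.05 and -0.24 (adjusted p = 0.508), with the mast cell protease CPA3 at 48.5 and 65.7 against 51.8 and 24.2 FPKM. Only 4 T cell and NK cell genes were tested, too few for a list test, and CD3D stood at 2.15 and 10.1 against 2.12 and 3.07 FPKM. The macrophage list was called lower without young 1 (adjusted p = 0.0051) and without old 2 (adjusted p = 3.9e-06) and higher without old 1 (adjusted p = 0.0135).

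Skeletal muscle genes, which a full-thickness biopsy can carry from the layer under the skin, were called higher with the preset correlation (adjusted p = 1.3e-06), with adjusted p = 0.484 with an estimated correlation. Of 21 genes, 17 were higher in both numbers and 1 was lower in both, with medians of 0.47 and 0.61, and 0 passed over all genes or adjusted over the list alone. TNNT1, a slow-fibre troponin, stood at 15.1 and 14.2 FPKM in young 1 and 2 and 39.9 and 30.4 FPKM in old 1 and 2, and ACTN3 of fast fibres at 37.0 and 11.3 against 67.0 and 62.9 FPKM. ACTA1, a skeletal muscle actin, stood at 1349 and 871 against 1832 and 1332 FPKM, and MB, or myoglobin, at 468 and 940 against 420 and 1532 FPKM. The summed muscle FPKM differed by 0.37 on the log2 scale in number 1 and 0.59 in number 2, and the summed red cell FPKM by -2.90 and -2.29. The muscle call ended without young 2 (adjusted p = 0.0823).

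Vessel, fat and nerve lists were not called. The 14 endothelial genes had medians of -0.21 and -0.05 (adjusted p = 0.770), with LYVE1, a marker of lymphatic vessels, at 17.5 and 9.68 FPKM in young 1 and 2 and 22.01 and 30.1 FPKM in old 1 and 2. The 11 pericyte and smooth muscle genes had medians of 0.00 and -0.37 (adjusted p = 0.549), with ACTA2 at 14.3 and 14.6 against 13.9 and 2.80 FPKM. The 13 adipocyte genes had opposite medians of 0.31 and -0.70 (adjusted p = 0.785), with ADIPOQ, or adiponectin, at 154 and 45.1 against 226 and 8.41 FPKM. The 12 Schwann cell and nerve genes also had opposite medians, 0.48 and -0.67 (adjusted p = 0.655). Only 4 Merkel cell genes were tested, with medians of 0.40 and -0.28. Without old 1 the adipocyte list was called lower (adjusted p = 0.0135).

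Genes of cell division were called lower with the preset correlation (adjusted p = 1.3e-05), with adjusted p = 0.484 with an estimated correlation. Of 22 cell cycle genes, 14 were lower in both numbers and 2 higher in both, with medians of -0.20 and -0.59, and 0 passed over all genes or adjusted over the list alone. PCNA, the sliding clamp of DNA replication, stood at 15.5 and 18.9 FPKM in young 1 and 2 and 8.19 and 5.96 FPKM in old 1 and 2, and MCM4 of the replicative helicase at 5.999 and 4.32 against 2.99 and 0.726 FPKM. The call ended without young 2 (adjusted p = 0.638) and without old 1 (adjusted p = 0.273).

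Cell cycle inhibitor and tumour suppressor genes were called higher with the preset correlation (adjusted p = 9.4e-05), with adjusted p = 0.562 with an estimated correlation. Of 35 genes, 16 were higher in both numbers and 2 lower in both, with medians of 0.17 and 0.23. In this list 0 passed over all genes or adjusted over the list alone, and 1 passed adjusted over the list alone with the library number as a term. The list is not independent evidence of its direction, since some members were put on it because the study was thought, from memory, to have named them. Without the 10 tested members of that kind, 25 genes had medians of 0.11 and 0.01 and the list was not called (adjusted p = 0.508). The 2 members that the naming rule gave were both among those 10. SFRP1, a secreted WNT inhibitor, stood at 2.26 and 2.33 FPKM in young 1 and 2 and 8.68 and 5.97 FPKM in old 1 and 2, and SOCS3, a cytokine signalling inhibitor, at 1.70 and 2.63 against 3.86 and 23.1 FPKM. The call ended without young 2 (adjusted p = 0.118) and without old 2 (adjusted p = 0.0754).

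The p53 target and immediate early lists were called higher, largely from the number 2 libraries. Of 24 p53 targets, 9 were higher in both numbers and 0 lower in both, with medians of 0.09 and 0.39 (adjusted p = 0.0071 with the preset and 0.484 with an estimated correlation). EDA2R, a receptor gene induced by p53, stood at 0.558 and 0.154 FPKM in young 1 and 2 and 4.03 and 0.901 FPKM in old 1 and 2. Of 25 immediate early genes, 11 were higher in both numbers and 2 lower in both, but the median was -0.10 in number 1 and 0.92 in number 2 (adjusted p = 1.6e-04 with the preset and 0.806 with an estimated correlation). FOS stood at 13.8 and 6.72 against 8.93 and 91.7 FPKM. In both lists 0 members passed over all genes or adjusted over the list alone. Without old 2 the p53 list turned to the lower side (adjusted p = 0.997), and it lost its call without young 1 (adjusted p = 0.427), without young 2 (adjusted p = 0.0823) and with a minimum mean of 5 FPKM (adjusted p = 0.136). The immediate early list turned lower without old 2 (adjusted p = 0.0138) and lost its call without young 1 (adjusted p = 0.405).

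Other stress and ageing lists were not called. Insulin and IGF signalling had medians of 0.09 and 0.30 over 31 genes (adjusted p = 0.0624), with IGF1 at 9.96 and 2.92 FPKM in young 1 and 2 and 1.97 and 1.29 FPKM in old 1 and 2. Heat shock and chaperone genes had medians of 0.22 and -0.01 (adjusted p = 0.0961), with adjusted p = 0.685 with an estimated correlation. The list passed when small structural RNA and mitochondrial loci were left out (adjusted p = 0.0189), but not with the library number as a term as well (adjusted p = 0.0902). The 20 senescence-associated secretion genes had medians of 0.15 and 0.13 (adjusted p = 0.748), with IGFBP3 at 14.7 and 24.3 against 27.2 and 165 FPKM and the chemokine CCL2 at 1.3 and 1.84 against 2.14 and 12.2 FPKM. Medians in number 1 and number 2 were -0.03 and -0.09 for antioxidant and NRF2 genes, 0.08 and -0.23 for DNA repair, 0.02 and -0.13 for sirtuin and telomere genes, and -0.02 and 0.20 for autophagy and lysosome genes. They were -0.03 and -0.09 for oxidative phosphorylation, -0.06 and 0.06 for hypoxia and glycolysis, and 0.10 and 0.08 for DNA methylation and chromatin genes. With 1 library left out, insulin and IGF signalling passed without young 1 (adjusted p = 0.0085), autophagy and lysosome genes passed without old 1 (adjusted p = 0.0261), and oxidative phosphorylation passed lower without young 1 (adjusted p = 7.5e-04) or old 2 (adjusted p = 1.7e-04) and higher without young 2 (adjusted p = 0.0024) or old 1 (adjusted p = 0.0135). BNIP3, a mitochondrial protein induced in low oxygen, stood at 25.1 and 10.6 against 29.4 and 162 FPKM.

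Signalling lists had medians of 0.22 and -0.13 for WNT, 0.14 and -0.10 for TGF-beta and BMP, -0.10 and 0.02 for the interferon response and -0.04 and 0.08 for the circadian clock, with lowest adjusted p = 0.435 among them. The 39 ribosomal protein genes had medians of 0.52 in number 1 and -0.44 in number 2 (adjusted p = 0.884), and were called lower without young 1 (adjusted p = 2.9e-07) or old 2 (adjusted p = 1.7e-04) and higher without young 2 (adjusted p = 1.1e-10) or old 1 (adjusted p = 0.0054). Of the 13 sex-linked genes listed, 0 were found by name, so the sex of the animals was not examined here. With fry in place of camera, 0 of 39 lists passed (lowest adjusted p = 0.997).

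**Figure D2:**
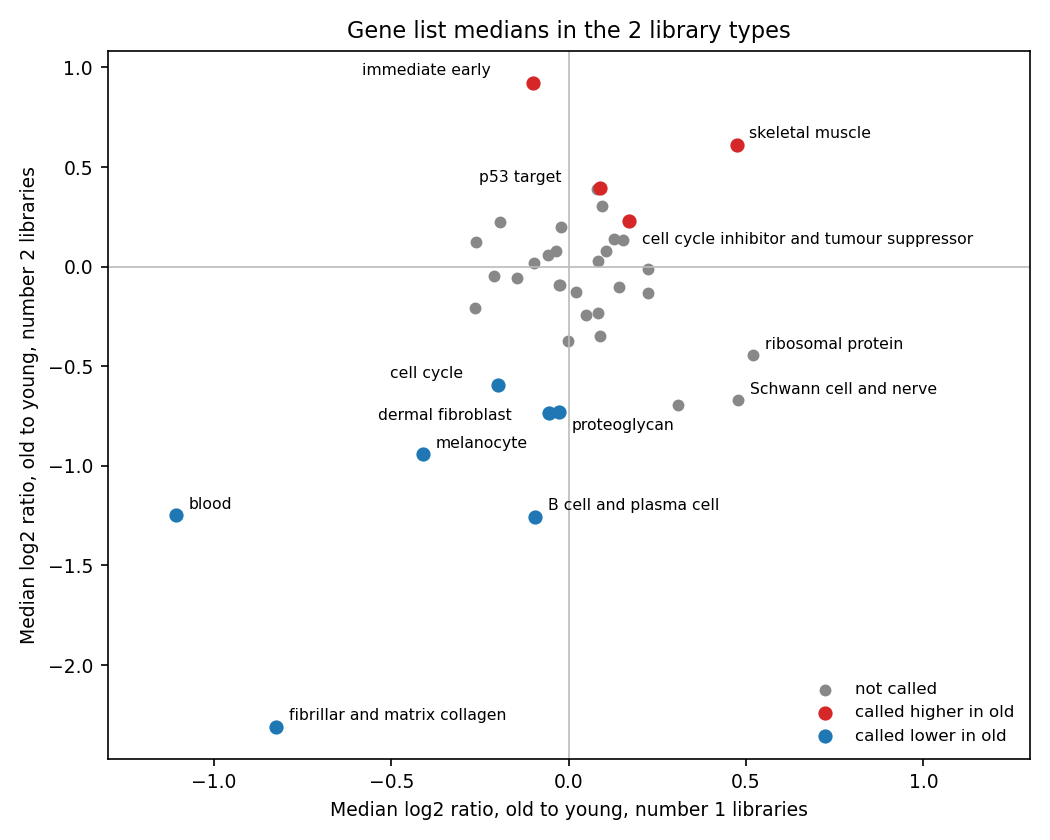
Median log2 ratio of old to young over the tested members of each of 39 gene lists, in the number 1 libraries on the x axis and the number 2 libraries on the y axis, with lists called by camera at its preset correlation in red (higher) and blue (lower). The collagen list lies at -0.82 and -2.31, the lowest value on the y axis, the red cell list at -1.11 and -1.25, and the ribosomal protein list has opposite signs, 0.52 and -0.44.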

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

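The difference described here was not tested, since each library number held 1 library per age, and the search for it was chosen after the data were seen.

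Of the 39 ribosomal protein genes, 37 (94.9%) had opposite old to young directions in the 2 library numbers. In number 1 the old library was higher for 38 of them, with a median log2 ratio of 0.52, and in number 2 it was higher for 1, with a median of -0.44. Over all 12753 tested genes, 49.1% had opposite directions, and no other of the 39 lists reached 80%. The correlation that camera estimated between the ribosomal protein genes was 0.96. They moved nearly as 1 unit, so the count of 37 is not one of independent genes. RPL6 stood at 212 and 435 FPKM in young 1 and 2 and 221 and 227 FPKM in old 1 and 2, and RPS6 at 48.6 and 212 against 66.4 and 100.4 FPKM. No explanation was tested.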

How the results depend on the processing

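The combinations with the library number, the removal of small structural RNA and mitochondrial loci, and the lists without some members were chosen after the data were seen. Limma called 0 genes higher and 0 lower with a pseudocount of 0.1, no filter, a minimum mean of 5 FPKM, scaling, no trend, robust moderation and adjusted p 0.1. With library number as a replicate block it called 1 higher and 2 lower, as it did with the block and scaling (lowest adjusted p = 0.0465) and with the block and a pseudocount of 0.1 (lowest adjusted p = 0.0253). With small structural RNA and mitochondrial loci left out it called 0 and 0, also with the block (lowest adjusted p = 0.0661), where log2 differences were -4.25 for C1QTNF6 and -4.12 for CPZ, against -4.31 and -4.17 before. Deviations from the age means correlated at 0.823 between same-numbered libraries, which 2 groups of 2 force to be equal for both numbers. With 1 library left out, genes called ranged from 0 to 24 higher and 0 to 32 lower, and lists called from 1 to 9 higher and 1 to 11 lower. In those fits the lone library of an age is assumed to vary like the others, and the fit has 1 residual degree of freedom. Camera with an estimated correlation called 0 lists higher and 0 lower, as did fry, and camera with the block and an estimated correlation (lowest adjusted p = 0.949). The camera tests with an estimated correlation rest on 2 residual degrees of freedom, or 1 with the block, so their lack of calls decides no list. Depth is unknown, so its effect on low genes was not examined.

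With 1 library left out, list adjusted p ran from 1.3e-04 (old 2) to 0.0135 (old 1) for suprabasal genes, 6.2e-05 (young 1) to 0.949 (young 2) for B cell genes and 3.9e-06 (old 2) to 0.124 (young 2) for macrophage genes. It ran from 0.0135 (old 1) to 0.997 (old 2) for p53 targets and 4.3e-13 (old 1) to 0.405 (young 1) for immediate early genes. For oxidative phosphorylation it ran from 1.7e-04 (old 2) to 0.0135 (old 1), and for ribosomal proteins from 1.1e-10 (young 2) to 0.0054 (old 1). Each of these lists turned direction in at least 1 such fit. Those fits mix the library number into the age difference, since the numbers are then unbalanced against the ages. The suprabasal, oxidative phosphorylation and ribosomal protein lists went lower without young 1 or old 2 and higher without young 2 or old 1. How much of each turn came from that mixing was not tested. Among lists not called in either fit, the direction turned 45 times over all settings, 13 of them without old 2.

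Named genes that passed no test also turned direction. The log2 difference of ELOVL4 was 1.9e-04 with scaling, with and without the block. With small structural RNA and mitochondrial loci left out it was 0.057 for ELOVL4, 0.060 for KRT10 and 0.032 for CD3G, with and without the block. The lowest and highest log2 differences with 1 library left out, named in parentheses, were KRT10 -0.79 (young 1) and 0.78 (young 2), KRTDAP -1.52 (young 1) and 0.87 (young 2) and then DSC2 -0.995 (old 1) and 0.18 (old 2). Those of further genes were KRT17 -0.62 (young 1) and 0.63 (young 2), Vim -0.093 (old 1) and 0.32 (old 2) and then PLVAP -1.51 (old 2) and 1.91 (old 1). Next came VWF -0.40 (young 2) and 0.021 (young 1), RGS5 -1.89 (old 1) and 1.22 (old 2) and then CD3D -1.64 (young 1) and 0.18 (young 2). Further values were CD3G -0.74 (old 1) and 0.62 (old 2), XBP1 -0.051 (young 1) and 0.82 (young 2) and then CD74 -2.13 (young 1) and 0.099 (young 2). They were followed by C1QA -0.97 (old 2) and 1.56 (old 1), CMA1 -1.47 (young 1) and 0.27 (young 2) and then SYP -0.89 (old 1) and 0.11 (old 2). The range also covered ENO2 -0.036 (old 1) and 0.19 (old 2), FABP4 -0.39 (old 1) and 0.98 (old 2) and then ADIPOQ -3.17 (old 1) and 1.42 (old 2). Those of further genes were ELOVL4 -0.062 (young 2) and 0.055 (young 1), PMP22 -0.41 (old 1) and 0.78 (old 2) and then MB -0.66 (old 2) and 1.21 (old 1). Next came FOS -0.11 (old 2) and 3.12 (old 1), TXNRD1 -0.065 (old 2) and 1.37 (old 1) and then RPL6 -0.95 (young 1) and 0.078 (young 2). Further values were RPS6 -1.37 (young 1) and 0.74 (young 2) and then H2AFZ -1.09 (young 1) and 0.048 (young 2).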

Other observations

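Chosen after their results were seen were the MHC class II list and the tests of fibroblast number, muscle dilution, scaling, the loss of small RNAs, poly(A) selection and muscle content, and the collagen folding, fatty acid and glucocorticoid tests were set before their values were seen.

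Genes that present antigen on MHC class II molecules were put on a list because of their values here, so no test of the list is given. Of 13 measured, 10 were lower in both numbers and 0 were higher in both, with median log2 ratios of -0.52 in number 1 and -0.87 in number 2. HLA-DRA, an alpha chain, stood at 96.8 and 154 FPKM in young 1 and 2 and 58.3 and 84.0 FPKM in old 1 and 2, and HLA-DQA1 at 146 and 143 against 77.1 and 49.5 FPKM. Among immune markers, log2 ratios in numbers 1 and 2 were -0.88 and -1.64 for CD207, -0.45 and -1.13 for FLT3 and -1.97 and -2.91 for MZB1 of antibody-secreting cells. Others differed, with -0.06 and 0.65 for C1QA and 1.03 and -0.27 for XBP1. The macrophage and dendritic cell list had medians of -0.26 and 0.12, and the B cell and plasma cell list -0.09 and -1.25.

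The 5 collagen transcripts of types I, III and V had median log2 ratios of -3.09 in number 1 and -6.22 in number 2. The tables argue against fewer fibroblasts as the whole cause of this fall, since 15 other fibroblast markers had medians of only -0.05 and -0.65. These markers lay 3.04 above the collagens in number 1 and 5.57 in number 2, against their median absolute deviations of 0.18 and 0.55. The 5 collagens were picked for their fall, so part of each gap was built in. The other 10 members of the collagen list had medians of -0.39 and -0.46, and fewer fibroblasts as a cause of their fall was not tested. The tables also argue against dilution by muscle, with keratinocyte marker medians of -0.051 and 0.31, and against scaling, after which the collagen medians were -3.16 and -6.15. Collagen folding and secretion genes had medians of -0.20 ± 0.16 and -0.57 ± 0.23 (SE over genes), at percentiles 0 and 0.02 of the matched random lists. Of 23 tested, 12 were lower in both numbers and 3 higher in both. The number 1 median did not reach the cutoff set beforehand, so a shared secretory programme could not be decided. Age, lower transcription in each fibroblast and differences between animals or biopsies may each account for the pattern and stay open as untested.

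The split of the libraries by number was examined with 24 histone loci, whose mRNAs mostly lack a poly(A) tail and are longer than most small RNAs. All 24 were higher in the number 1 library at both ages, with gaps to the median of all genes of 3.33 in young and 2.76 in old skin, against median absolute deviations of 1.00 and 0.90. The gap of 2.76 argues against a loss confined to RNAs shorter than these mRNAs. A loss by size that reached the length of histone mRNAs would give such a gap too, so it could not be decided. The same gap of 2.76 is what poly(A) selection in the number 2 libraries would need, a candidate explanation that the labels do not state, since they give ribosomal RNA removal for every sample. Other histone loci had been seen when this idea arose, and no biological explanation was tested.

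PDK4, PCK1 and ANGPTL4, genes that respond to fasting, were higher in the old library of both numbers, with median log2 ratios of 1.61 and 2.69. The 5 muscle transcripts with the highest mean over the 4 libraries lay 1.58 below these genes in number 1 and 2.08 in number 2, against spreads of 0.44 and 0.50. This cannot decide on more muscle in the old biopsies, since PDK4, PCK1 and ANGPTL4 were picked for their rise and a gap was partly built in. The list of 21 muscle genes had medians of 0.47 and 0.61, with 17 higher in both numbers and 1 lower in both. A glucocorticoid response in both numbers is argued against by a list median of -0.18 ± 0.17 (SE over genes) in number 1. In number 2 the median was 1.03 ± 0.35 (SE over genes), at percentile 100 of the matched random lists. There MT2A stood at 669 FPKM in young 2 and 1447 FPKM in old 2 and FKBP5 at 5.49 and 20.8 FPKM. PDK4 rose 52.4-fold in number 2 and 3.18-fold in number 1, so such a response in number 2 alone could not be decided. Fatty acid oxidation and fasting genes had medians of -0.0013 and 0.12, at percentiles 18.5 and 90.1 of the matched random lists, with members going both ways. The number 1 median met the cutoff set beforehand against a wider programme in both numbers. It lay past that cutoff by less than its SE over genes of 0.12, so a wider programme was left undecided. Age and feeding before sampling stay open as untested, and TRIM63, a muscle atrophy gene at 7.86 FPKM in young 2 and 249.6 FPKM in old 2, was lower in old 1 than in young 1.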
